A study of Hordeum vulgare with 12 samples.

How the data were processed

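RNA was extracted from whole inflorescences of barley (Hordeum vulgare) cultivar Golden Promise, a spring barley widely used for transformation. Per the labels' protocols, each biological replicate pooled 15 to 20 spikes, and libraries were made with the TruSeq RNA kit version 2, which does not mark the strand. The labels gave 12 samples in 4 groups of 3 libraries, from mutant and wild-type (WT) plants at the stages labelled W2.0 and W3.5. The design text of the series named W2.0 and W3.0 instead, and the sample labels were followed. The mutated gene is not named in the sources used here, where the genotype label is mutant, the series text speaks of FEA (FASCIATED EAR), and the names of the mutant's libraries and columns begin with F4, which is not explained.

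The deposited table held 4 columns, 1 per group, for 29014 gene identifiers. Its values were FPKM (reads scaled by gene length and library depth) that the authors had averaged over the 3 libraries of a group. This unit was read from the values, since no header or label states it. FastQC, HISAT2 2.0.0 and HTSeq 0.11.2 were named in the submitters' processing notes. The genome build, the annotation and the handling of reads that match several genes are not given in the sources used here. Genes with near-identical copies or overlapping neighbours therefore carry an unknown share of each other's reads. A single end or pair could not be told apart in the values, and "reads" below stands for either.

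The reads of single libraries were recovered from the group means. A mean of 3 FPKM values is a sum of 3 whole numbers of reads, each weighted by its library's depth, divided by the gene's length. Values were printed with 9 decimals below 1 and with 10 significant digits above. Ratios of low values between columns gave the relative depth of the 3 libraries behind each column, and all 9 ratios of 3 by 3 libraries were found for each pair of columns. The common scale was set as the smallest at which all 12 denominators came out whole, within a tolerance of 0.1. The largest distance from a whole number was 0.028. Residuals of the 1465 genes used had an SD of 2.87e-10 FPKM, against 2.89e-10 FPKM from rounding alone. Solutions were accepted only within rounding, so this match was built in and is no check of the depths. The denominators ran from 63298092 to 75896357 reads per library. Whole reads and a whole length were then searched for each gene, and a gene was accepted when 1 solution held a probability above 0.99. The search used python 3.11.15, numpy 2.4.6 and numba 0.67.0.

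Reads were recovered for 10931 genes (37.7%). On simulated data with dispersions of 0.02 to 0.15, 2021 of 2022 recovered genes had the right reads in all 12 libraries and the right length. Genes of larger dispersion were not simulated, so this share does not cover their library values. When the columns were shuffled against each other over 3000 genes, 14 were recovered, against 2324 of the same genes unshuffled. Recovery depended on level. It was 93.5% for genes whose highest group mean lay between 0.2 and 0.5 FPKM, 54.9% between 2 and 4 FPKM, 8.8% between 8 and 16 FPKM and 0.1% above 32 FPKM. It also depended on the spread between libraries. Of simulated genes with a highest group mean of 4 to 16 FPKM, 59.0% were recovered at a dispersion of 0.02 and 26.4% at 0.15. Which recovered library is which replicate in the labels is unknown, so libraries were named A, B and C within a group by falling depth. Recovered libraries were treated as the 3 biological replicates of the labels. Pairs of libraries within a group differed by 9.18 to 20.64 times the counting variance, by a chi-square over genes with at least 20 reads in the pair, so none was counted as a duplicate.

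Tests were run with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a mean-variance trend and 1 model of 4 group means over all 12 libraries. Genes entered with at least 1 FPKM in at least 3 libraries, which left 3947 genes. Their median was 146 reads per gene and library, and the central 90% ran from 15 to 572 reads. The model tested 5 contrasts, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale and understate changes of low genes. The tests, comparisons and rule for named genes were fixed before the data were examined. The plan had assumed gene counts per library and named limma on log2 values for a normalized unit, so that test was used. Of the count-based alternatives of the plan, limma-voom and RLE size factors were applied to the recovered reads, and the others were not run. Genes above about 16 FPKM had almost no recovered libraries and are described by the authors' group means, with no SD, n or test. The authors' means were compared for all 19367 genes with at least 1 FPKM in a group, whether tested or not. A 2-fold difference of these means is at least 1 on the log2(FPKM + 1) scale.

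On simulated reads with a dispersion of 0.04 and 200 of 3947 genes changed in the mutant at W2.0, limma called 72 of 100 genes changed 2-fold and 100 of 100 changed 4-fold. It gave 12 false calls and no wrong sign. Genes were named as follows. Among called genes with at least 5 CPM (reads scaled by library depth) in the higher group and no overlap of the 6 libraries compared, the 2 with the highest and the 2 with the lowest fold change were taken. The condition on overlap applied to the contrasts of 2 groups. A further condition, that a gene's description names a product, could not be applied. The files do not pair the identifiers with gene names, and 0 of 29014 identifiers matched the reference table of gene names used here. The 34 gene lists fixed beforehand and the check of the target gene were therefore not run. The digit in an identifier was read as its chromosome, and identifier order as gene order. Alternatives were other scalings, filters and pseudocounts, limma-voom, separate fits and leaving out each library. All 4 columns were used.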

Results

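Gene expression was measured by RNA-seq in barley inflorescences of a mutant and of wild type at 2 stages, W2.0 and W3.5. The title of the series names FASCIATED EAR genes and meristem size. In maize, mutants of genes with this name have enlarged and flattened inflorescence meristems. Each of the 4 groups held 3 libraries. Depth behind the FPKM values lay between 63298092 and 75896357 reads per library. The authors' group means listed 18228 genes at 1 FPKM or more in WT at W2.0, 18503 in the mutant at W2.0, 18138 in WT at W3.5 and 18197 in the mutant at W3.5. Values of single libraries are those recovered from these means, for the 3947 genes tested. The tested genes were of low to moderate level, with a median of 2.14 FPKM. Genes are given by identifier because the files do not pair them with names.

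Libraries separated by genotype and, in WT, by stage, while the separation by stage was less clear in the mutant. The first principal component of the tested genes held 20.7% of the variance and set the WT libraries of W3.5, at 11.4 to 18.46, apart from those of W2.0, at -15.15 to -0.85. The second held 19.7% and set the 6 WT libraries, at 2.72 to 15.52, apart from the 6 mutant libraries, at -13.81 to -5.05. The mutant's W3.5 libraries lay between -3.63 and 7.49 on the first component and its W2.0 libraries between -12.15 and -5.96. The mean correlation between libraries of different stages was 0.819 in the mutant and 0.814 in WT. On the third component (13.8%), mutant W2.0 library A stood at -11.65, near the mutant libraries of W3.5, while libraries B and C stood at 10.43 and 19.41. Library A correlated with the mutant W3.5 libraries at a mean of 0.847 and with B and C at 0.794. The mean correlation between libraries of a group was 0.806 in the mutant at W2.0, against 0.872, 0.892 and 0.871 in WT at W2.0, WT at W3.5 and the mutant at W3.5. The median coefficient of variation of genes with at least 100 reads was 22.2% in the mutant at W2.0 and 17.1% to 18.7% in the other groups.

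**Figure D1:**
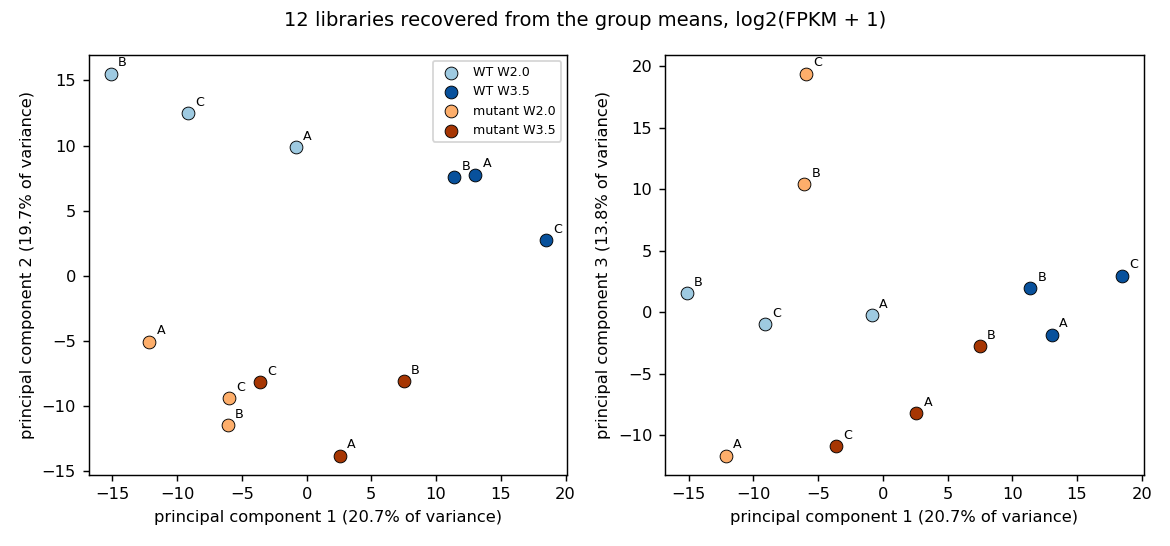
Principal components of the 12 recovered libraries, from log2(FPKM + 1) of 3947 genes, with component 1 against component 2 on the left and against component 3 on the right. Points are libraries, coloured by group and lettered A to C by depth. Component 2 separates all 6 WT from all 6 mutant libraries, and component 3 holds mutant W2.0 library A at -11.65 apart from B and C at 10.43 and 19.41.

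The first comparison asked which genes differed between mutant and WT at W2.0. HORVU5Hr1G108870 and HORVU5Hr1G064100, both on chromosome 5H, were near 0 in WT and expressed in the mutant. HORVU5Hr1G064100 rose from 0.0608 ± 0.0306 FPKM in WT to 5.2 ± 1.92 FPKM in the mutant (SD, n = 3), a log2 fold change of 2.50 ± 0.20 (SE). HORVU5Hr1G108870 rose from 0.0388 ± 0.0344 to 6.29 ± 4.78 FPKM (SD, n = 3), by 2.57 ± 0.39 on the log2 scale. Its call was lost with limma-voom. HORVU7Hr1G087690 on 7H fell from 7.3 ± 2.65 to 0.0648 ± 0.112 FPKM (SD, n = 3), and HORVU4Hr1G065270 on 4H from 5.97 ± 1.12 to 0.215 ± 0.189 FPKM (SD, n = 3). Their log2 fold changes were -2.92 ± 0.22 and -2.52 ± 0.20 (SE). The limma adjusted p of these genes lay at 0.00202 for HORVU5Hr1G108870 and at 8.65e-06 or below for the other 3. In all, 64 of 3947 genes changed, 46 up and 18 down, with a median size of 1.44 on the log2 scale, and 460 had an unadjusted p under 0.05 against 197.4 expected by chance. Without mutant W2.0 library A, which stood apart on the third component, 127 genes passed. Over the 19367 genes at 1 FPKM or more, the authors' mean was at least 2-fold higher in the mutant for 496 genes and lower for 368. Of the 112 tested genes with a difference of this size, 52.7% were called.

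At W3.5, the same comparison again gave HORVU5Hr1G064100 and HORVU5Hr1G108870 as the genes that rose most among those eligible. HORVU5Hr1G064100 stood at 0.0552 ± 0.0136 FPKM in WT and 7.69 ± 0.314 FPKM in the mutant (SD, n = 3), a log2 fold change of 3.04 ± 0.20 (SE; limma adjusted p = 1.88e-06). HORVU5Hr1G108870 stood at 0.0277 ± 0.048 and 7.08 ± 3.07 FPKM (SD, n = 3), a difference of 2.91 ± 0.39 that passed with limma-trend and not with limma-voom. HORVU4Hr1G065270 fell again, from 6.01 ± 1.66 to 0.351 ± 0.0332 FPKM (SD, n = 3). By the authors' means HORVU4Hr1G065250, its neighbour in identifier order among genes at 1 FPKM or more, went the other way. This neighbour stood at 0.122 and 0.281 FPKM in WT at W2.0 and W3.5, and at 3.211 and 4.396 FPKM in the mutant. An exchange of reads between these neighbours was not tested. HORVU4Hr1G078460 on 4H fell from 6.99 ± 1.06 to 0.593 ± 0.12 FPKM (SD, n = 3), a log2 fold change of -2.32. In total 72 genes changed, 47 up and 25 down, with a median size of 1.41, and 486 had an unadjusted p under 0.05. Among the authors' means, 387 genes were at least 2-fold higher in the mutant and 156 lower. Of the 89 tested genes with such a difference, 66.3% were called.

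**Figure D2:**
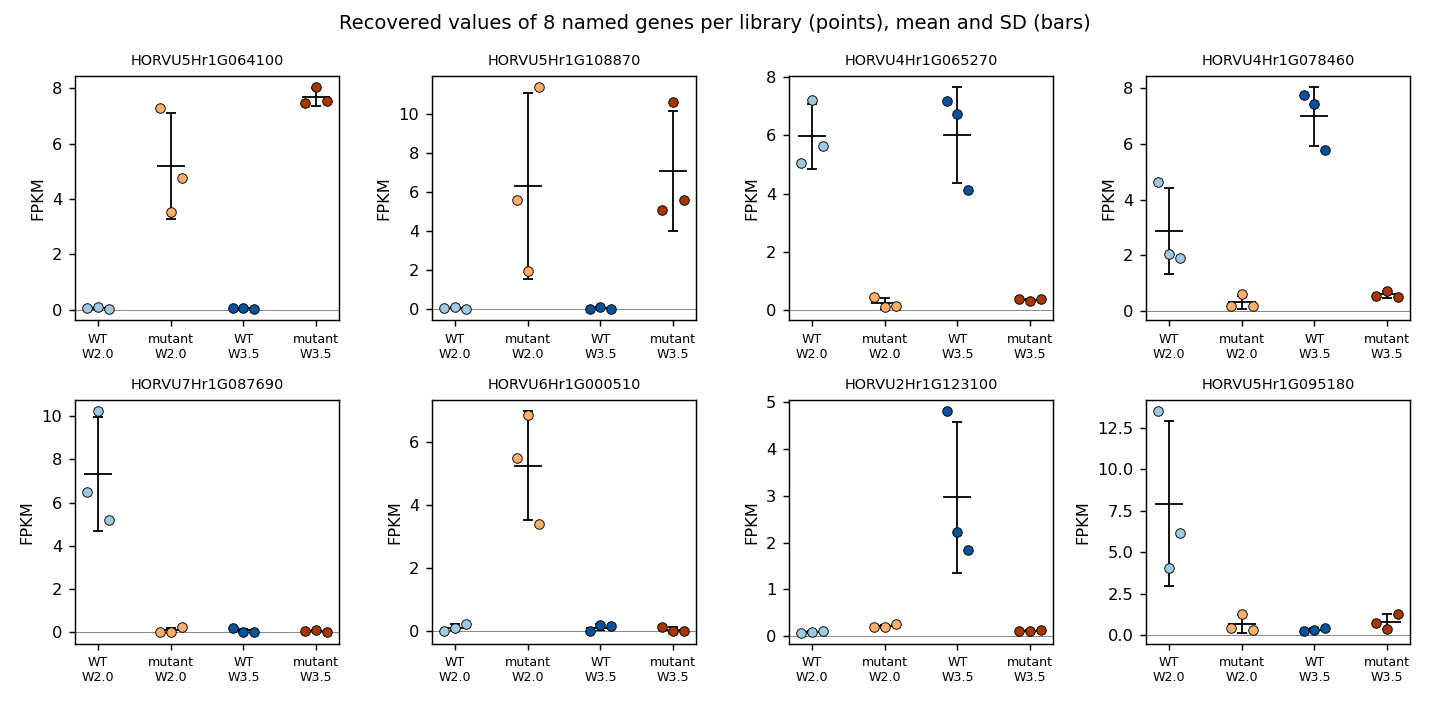
FPKM of 8 named genes in the 4 groups. Points are the 3 recovered libraries of a group, horizontal bars the mean and vertical bars the SD. In the upper row, HORVU5Hr1G064100 and HORVU5Hr1G108870 were near 0 in WT at both stages, and HORVU4Hr1G065270 and HORVU4Hr1G078460 were lower in the mutant at both. In the lower row, each gene had its highest mean in a single group, such as 7.3 FPKM for HORVU7Hr1G087690 in WT at W2.0.

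The genotype comparisons at W2.0 and W3.5 share no library, and their calls were set against each other. Of the genes that rose in the mutant at W2.0, 32 also rose at W3.5, where independent lists would share 0.55. Of those that fell, 8 fell at both stages, against 0.11 by chance, and none of the called genes had opposite calls. Both contrasts drew each gene's spread from all 12 libraries, so their calls are not fully independent and these chance values can be too low. The 46 genes that rose at W2.0 had a median log2 fold change of 1.44 there and 1.43 at W3.5, and 42 had the same sign. The 18 that fell had medians of -1.44 and -0.61, and 12 had the same sign. Across the 3947 genes the fold changes of both stages correlated with r = 0.369 (jackknife SE 0.124), where genes are not independent replicates. Jackknife SEs of correlations, here and below, treat the 12 libraries as 1 sample and ignore the groups. Spearman's coefficient was 0.179. Over the authors' means of 19367 genes, r was 0.206. There, 150 genes were at least 2-fold higher at both stages against 9.9 by chance, and 41 lower against 3.0. Of the 368 genes at least 2-fold lower in the mutant at W2.0, 139 (37.8%) had the same sign at W3.5, with a median of 0.12 on the log2 scale, while 353 of the 496 higher ones (71.2%) did. A further 55 genes were lower in the mutant at W2.0 and higher at W3.5, against 7.4 by chance, and 13 the reverse, against 4.0. These means have no replicate check, and genes of large spread can enter both lists, so these chance values can be too low.

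**Figure D3:**
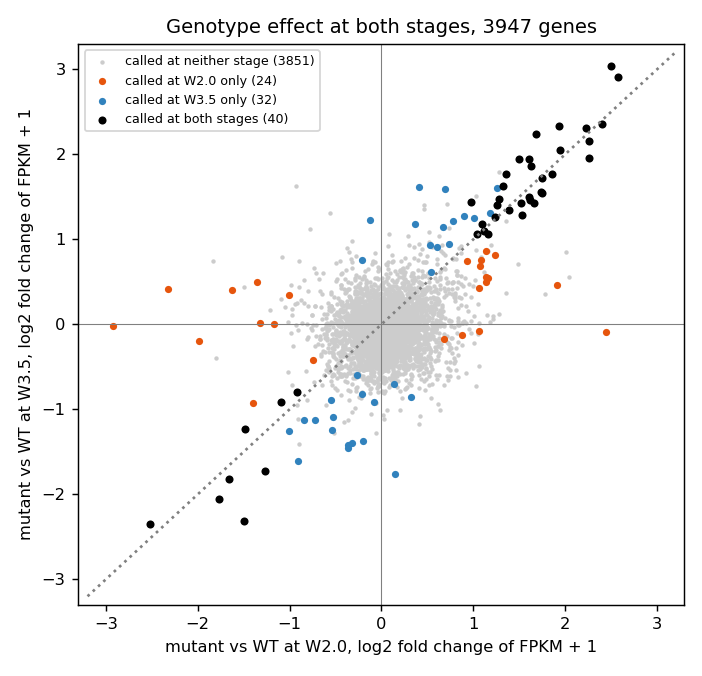
Log2 fold change of FPKM + 1 between mutant and WT at W2.0 (x axis) and at W3.5 (y axis) for 3947 genes. Black points are the 40 genes called at both stages, orange the 24 called at W2.0 and not at W3.5, blue the 32 called at W3.5 and not at W2.0, and grey the 3851 others. The dotted line marks equal change, and all 40 genes called at both stages lie in the lower left or upper right quadrant.

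A part of the genotype difference took the form of genes present in one genotype and nearly absent from the other at both stages. By the authors' means, 48 genes were under 0.5 FPKM in WT and at least 2 FPKM in the mutant at both stages, and 5 genes showed the reverse. The same rule over crossed pairs of groups, which share neither genotype nor stage, gave 2 and 5 genes. The number of WT-only genes does not exceed this background, although HORVU4Hr1G065270, called at both stages, is 1 of them. Another WT-only gene, HORVU6Hr1G018030, stood at 79.459 and 70.902 FPKM in WT at W2.0 and W3.5, and at 0.219 and 0.056 FPKM in the mutant. The lower of the mutant means had a median of 3.5 FPKM over the 48 genes and reached 102.0 FPKM, and 4 genes were at 20 FPKM or more. All 48 means were within 2-fold between the stages of the mutant, with ratios of 0.57 to 1.54. Reads of single libraries were recovered for 18 of the 48, and 17 had every mutant library above every WT library, although the genes were chosen on the means of these libraries. Recovery also favours genes whose libraries are alike, which makes such a result more likely. The highest WT library of the 18 stood at 0.679 FPKM and the lowest mutant library at 0.166 FPKM.

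In WT, the stage comparison asked what changed from W2.0 to W3.5. HORVU7Hr1G087690 fell from 7.3 ± 2.65 to 0.0528 ± 0.0914 FPKM and HORVU5Hr1G095180 on 5H from 7.92 ± 4.98 to 0.323 ± 0.0844 FPKM (SD, n = 3). Their log2 fold changes were -2.94 ± 0.22 and -2.61 ± 0.33 (SE). HORVU2Hr1G123100 on 2H rose from 0.0944 ± 0.0184 to 2.97 ± 1.62 FPKM (SD, n = 3), by 1.79 ± 0.24. HORVU2Hr1G025380 on 2H rose from 2.04 ± 0.115 to 5.75 ± 1.07 FPKM (SD, n = 3), by 1.14 ± 0.26, and was no longer called with RLE size factors, without the filter, or without any 1 of the 6 WT libraries or mutant W3.5 library B. In total 88 genes changed, 30 up and 58 down, and 665 had an unadjusted p under 0.05. The split depended on scaling, because the median of the tested genes was 0.106 higher at W3.5 on the log2 scale. With RLE size factors, which bring this median to 0, 10 genes rose and 69 fell, and with upper-quartile scaling 15 rose and 63 fell. The count fell to 35 and 30 without WT W2.0 library B or C, to 26, 23 and 21 without WT W3.5 library A, B or C, and to 52 without mutant W3.5 library B. The split depended on single libraries too, since 3, 3 and 2 genes rose without WT W3.5 library A, B or C. It was 54 with a log2 fold change of at least 1. The authors' means were at least 2-fold lower at W3.5 for 788 genes and higher for 209, with a median log2 difference of 0.058 over 19367 genes.

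In the mutant, 3 genes changed between the stages. HORVU6Hr1G000510 on 6H fell from 5.26 ± 1.74 FPKM at W2.0 to 0.0507 ± 0.0879 FPKM at W3.5 (SD, n = 3), a log2 fold change of -2.54 ± 0.22 (SE; limma adjusted p = 0.000103). HORVU2Hr1G038040 on 2H fell from 7.11 ± 2.09 to 1.87 ± 0.414 FPKM (SD, n = 3), by 1.47 on the log2 scale. The third gene, HORVU1Hr1G041960 on 1H, is named outside the rule, after its values were seen. It rose from 0.495 ± 0.424 to 3.74 ± 0.551 FPKM (SD, n = 3), by 1.70 ± 0.22. It also rose in WT, from 0.673 ± 0.216 to 2.21 ± 0.415 FPKM (SD, n = 3). With limma-voom no gene passed, although 365 had an unadjusted p under 0.05, and limma-trend gave 396 such genes. Without mutant W2.0 library A, 5 genes passed. The call of HORVU2Hr1G038040 was lost without the filter, in a fit of the 6 mutant libraries alone, and without mutant W2.0 library B or C, WT W2.0 library C, WT W3.5 library B or C, or any 1 of the mutant W3.5 libraries. The authors' means were at least 2-fold lower at W3.5 for 477 genes and higher for 142, but of 53 tested genes with such a difference 5.7% were called.

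The stage effects of both genotypes share no library. Of the 58 genes that fell in WT, 46 had the same sign in the mutant, with a median log2 fold change of -1.28 in WT and -0.43 in the mutant. Of the 30 that rose in WT, 20 had the same sign, with medians of 0.94 and 0.12. One gene was called up in both. These genes were selected in WT, which enlarges their WT values. Across 3947 genes the stage effects correlated with r = 0.323 (jackknife SE 0.158), and with r = 0.311 over the authors' means. It was 0.214 without mutant W2.0 library A, and 5 of 100 splits of the libraries gave a correlation as large, the real one included. By those means 166 genes were at least 2-fold lower at W3.5 in both genotypes, against 19.4 by chance, and 33 were higher, against 1.5. Opposite changes also exceeded chance, with 22 genes lower in WT and higher in the mutant against 5.8, and 12 genes higher in WT and lower in the mutant against 5.1. These lists rest on means without a replicate check, and genes of large spread can enter both, so these chance values can be too low.

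The interaction tested whether the genotype effect differed between stages. It called 2 genes. HORVU7Hr1G087690 stood at 7.3 ± 2.65 FPKM in WT at W2.0 and at 0.0648, 0.0528 and 0.0341 FPKM in the mutant at W2.0, WT at W3.5 and the mutant at W3.5, with an interaction of 2.90 ± 0.31 (SE; limma adjusted p = 0.00121). HORVU6Hr1G000510 stood at 5.26 ± 1.74 FPKM in the mutant at W2.0 and at 0.118, 0.119 and 0.0507 FPKM in WT at W2.0, WT at W3.5 and the mutant at W3.5, with an interaction of -2.54 ± 0.32 (SE; limma adjusted p = 0.00317). HORVU2Hr1G123100 was highest in WT at W3.5 and HORVU5Hr1G095180 in WT at W2.0, but their interactions of -1.90 ± 0.34 and 2.73 ± 0.47 did not pass, with limma adjusted p of 0.0768 and 0.07. An unadjusted p under 0.05 was reached by 335 genes. No gene passed with limma-voom (319 unadjusted) or with a pseudocount of 0.1 (329 unadjusted). Without WT W2.0 library B, mutant W2.0 library A or B, or WT W3.5 library C, 4 genes passed. The mutant effect was compared last with the mean stage effect of both genotypes, which asks whether mutant libraries sat earlier or later than WT. Across genes r was 0.098 at W2.0 and -0.15 at W3.5, with jackknife SEs of 0.249 and 0.168. These effects share libraries, and unchanged groups of the same spread gave -0.145 and 0.033, which lie less than 2 of these SEs away. Without mutant W2.0 library A the value at W2.0 turned to -0.078, and without mutant W3.5 library C the value at W3.5 was -0.031. The covariances were 0.011 and -0.0168, against -0.0075 and 0.0015 in unchanged groups.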

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

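The tests of the on and off genes and of the spread, and the thresholds for the splits of the 5 gene counts and of the first 2 correlations, were written down after their results were seen. The splits for the mutant effect against the stage effect and the test of the position of mutant W2.0 library A were set before their results were seen. The 2 interaction genes were singled out because their genotype effect differed between the stages by the interaction test. HORVU7Hr1G087690 had an interaction of 2.90 on the log2 scale, with its signal in WT at W2.0, and HORVU6Hr1G000510 one of -2.54, with its signal in the mutant at W2.0. Other splits gave as many genes in 12 of 100 drawn splits, the real one included, so chance is not excluded as a source of a count of 2. The highest other split gave 127 genes. It swaps the genotypes at 1 stage, so that it measures the mean genotype effect, and the highest of the rest gave 3.

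The genotype counts and the stage counts rest on 3 libraries against 3, which make 10 splits, too few for a share under 0.05. The real split alone reached its own count in each comparison (1 of 10). At W2.0 the genotype gave 64 genes and the highest other split 6, and at W3.5 it gave 72 against 1. The stages gave 88 against 0 in WT and 3 against 1 in the mutant. The correlation of the mutant effects of both stages (0.369) was reached by 1 of 100 splits, the real one, with 0.317 as the highest other. This share is the smallest that 100 splits can give and lies under 0.05, without adjustment for the other split tests. Spearman's coefficient and the authors' means were not tested in this way. The correlation of the stage effects (0.323) was reached by 5 of 100 splits, with 0.419 as the highest other, so chance is not excluded. The correlations of the mutant effect with the stage effect, 0.15 or less in size, were reached by 7 of 10 splits at W2.0, with 0.27 as the highest, and by 5 of 10 at W3.5, with 0.249 as the highest.

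The first pattern weighed is the set of 48 genes on in the mutant and near 0 in WT at both stages, for which spread between libraries alone is argued against by the crossed pairs of groups, where the same rule found at most 5 genes. A single chromosome segment that differs between the lines is argued against by position, since 22.9% of the genes lay on the fullest chromosome, 6H. This chromosome held 11 of the 48 genes, but only 2163 of the 19367 genes at 1 FPKM or more. Of the 48, 8 had a neighbour in identifier order that was 2-fold or more higher in the mutant at both stages. Position thus argues against 1 segment for all 48 genes, and not against smaller groups of neighbours. Reads assigned to a neighbouring copy stay open, since 4.2% had a neighbour in identifier order that was 2-fold or more lower in the mutant, but for only 6 of the 48 was a neighbour of a level at which such a loss would show. Sequence differences between the lines at many loci cannot be told apart from an effect of the mutation, which was not tested separately, because each line is 1 genotype, and the genes lay on 7 chromosomes.

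The second pattern is the smaller number of genes called between stages in the mutant (3) than in WT (88). A larger spread between the mutant W2.0 libraries stays open. The variance of the stage effects left after subtracting the replicate spread was 0.0267 in the mutant and 0.101 in WT. Leaving out each library of the genotype gave 0.0022 to 0.0661 in the mutant and 0.0729 to 0.144 in WT. These ranges do not overlap, the outcome written down as arguing against this explanation. The difference of 0.0743, however, had a jackknife SE of 0.0612, taken over libraries within groups and too large to decide. Whether mutant W2.0 library A is of a later stage cannot be told by its position. Along the 88 genes called in WT its median lay -0.1 from libraries B and C, where positive values point towards W3.5. Libraries B and C, set against the others of their group, stood at 0.01 and 0.12. The sign is not that of a later stage. However, the whole stage effect of the mutant on these genes was 0.29, or 0.26 without library A (1.08 in WT). Both lie below the 0.5 the test asked for, so it cannot decide. Over all tested genes, library A correlated with the mutant W3.5 libraries at a mean of 0.847 and with its own group at 0.794, and leaving it out gave 5 genes in place of 3. A smaller change between stages in the mutant, or a difference in the true stage of the plants collected, remains open as a hypothesis, and the interaction test called 2 genes.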

How the results depend on the processing

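Alternatives other than the stricter recovery threshold and the authors' means were chosen before the data were examined. No paired analysis was possible because the recovered libraries carry no replicate number. Of the count-based alternatives, limma-voom and RLE size factors were run on the recovered reads. The others were left out, and the gene lists were not run because the identifiers carry no names. The 64 and 72 genes of the genotype comparisons stayed within 1.5 times under all 10 other settings, which kept 44 to 63 and 48 to 67 of them. Leaving out each library gave 56 to 127 genes at W2.0 and 48 to 82 at W3.5. In WT between stages (88 genes), the count was 54 with a log2 fold change of at least 1 and 58 with the stricter recovery threshold, which tests fewer genes, and 21 to 96 leaving out each library. In the mutant (3 genes), limma-voom gave 0 and leaving out a library 2 to 5. For the interaction (2 genes), limma-voom and a pseudocount of 0.1 gave 0, a filter of 1 CPM gave 5 and a pseudocount of 5 gave 4. Leaving out a library gave 2 to 4. The stricter recovery threshold gave 1, because HORVU6Hr1G000510 did not reach it and was not tested. HORVU5Hr1G064100, HORVU4Hr1G065270, HORVU5Hr1G095180 and HORVU2Hr1G025380 did not reach it either, so the library values of these genes are less certain. No gene called in the 5 contrasts changed sign under these settings. Where no construction explains a difference, the cause was not tested. The correlation of the mutant effects (0.369) was 0.179 by Spearman's coefficient and 0.206 over the authors' means, and 0.266 to 0.404 leaving out each library. That of the stage effects (0.323) ran from 0.214 to 0.385. The correlation of the mutant effect with the stage effect at W2.0 (0.098) ran from -0.078, where it reversed, to 0.257, and at W3.5 (-0.15) from -0.233 to -0.031. Named genes kept their sign under all settings run, and 12 of 150 values under other settings and 15 of 192 leaving out a library lost their call. Recovery limits the tests to genes of low and moderate level, because 8.8% of genes between 8 and 16 FPKM and 0.1% above 32 FPKM could be recovered. It also favours genes whose libraries are alike. The spread, the p-values and the numbers of genes called describe such genes and can be too favourable for the rest.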

Other observations

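All tests in this part were chosen after the data were seen. Genes that were at least 2-fold higher in the mutant at both stages, by the authors' means, lay next to each other more often than in shuffled order. In identifier order along the chromosomes, 13 neighbouring pairs were both higher, against 1.1 expected from 10000 shuffles of the genes and 7 in the highest shuffle (permutation p = 0.0001, the smallest that the shuffles can give). Pairs with both genes lower numbered 2, against 0.08 expected (permutation p = 0.003). Pairs with 1 higher and 1 lower gene numbered 3, against 0.6 (permutation p = 0.02). HORVU4Hr1G065250 and HORVU4Hr1G065270 are 1 pair of the last kind. Adjusted over these 3 tests, the p-values were 0.0003, 0.0045 and 0.02. The shuffles treat genes as independent, while neighbours can share reads, and the means have no replicate check. The expected numbers and p-values can thus be too low, and the stage lists were not tested in the same way. Genes higher at both stages were found on every chromosome, from 17 on 3H to 26 on 6H, and a further 7 were on unplaced sequence. The rule for on and off genes was also applied to the stages. It found 8 genes at W2.0 that were near 0 at W3.5 in both genotypes, and 0 genes of the reverse kind. Over crossed pairs of groups, which share neither genotype nor stage, the rule found 2 and 5 genes, so the count of 8 is hardly distinct from this background.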
